A study of Xenopus laevis with 30 samples.

How the data were processed

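Messenger RNA of Xenopus laevis embryos of the Nasco strain was measured in 30 libraries: whole embryos and left, right, dorsal and ventral half-embryos, at stages 10.5 and 12, with 3 libraries in each of the 5 groups per stage. Per the labels' protocols, half-embryos were cut at stage 8 in Barth's solution and cultured in a dilution of it, and embryos were cultured in diluted Marc's Modified Ringer. As the labels read, medium and bisection therefore changed together between half-embryos and whole embryos, and no comparison with whole embryos separates them. RNA was isolated with an Absolutely RNA kit, poly(A) RNA was made into libraries with the TruSeq kit V2, which keeps no strand, and single-end reads were taken on an Illumina Hi-Seq instrument, per the labels' protocols. The submitters' processing notes name TopHat2 2.09 and DESeq, for which they give no version. The tool that counted reads is not given in the sources used here.

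The authors deposited 1 table of RPKM values per stage, reads scaled by gene length and by library depth, per the file headers. The genes are models of the JGI9.1 laevis annotation, and human symbols come from a protein search against the human proteome, per the file headers. The tables hold 16673 genes at stage 10.5 and 15596 at stage 12, of which 9827 and 9246 are named by a gene symbol, 5514 and 5176 by a model ID with a human symbol, and 1332 and 1174 by a model ID without one. Only genes with an average RPKM above 1 are listed, per the file headers, and 20 listed genes at stage 12 lay below 1, the lowest at 0.995. RPKM values sum to 415945 to 449703 per library at stage 10.5 and to 448602 to 465879 at stage 12. In 100% of genes the values of a row were whole multiples of a common step within a relative tolerance of 3e-09, which gave the whole reads behind them. The median was 88 reads per gene and library at stage 10.5 and 58 at stage 12, and an RPKM of 1 rested on a median of 11.0 and 8.40 reads. The 10 genes with most reads took 3.37% to 5.07% of a library at stage 10.5 and 5.69% to 6.98% at stage 12. The recovery was tested on 15596 simulated genes, of which 100% came back exactly up to a common factor and 0.0128% with a factor above 1. Coordinates are not printed, since the reference at hand was of another assembly and was not used here.

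Groups and replicate numbers were taken from the sample titles. The planned test for RPKM values was used in place of the count test planned for count tables: limma 3.58.1 in R 4.3.3, with its trend option, on log2(RPKM + 1), for genes at an RPKM of 1 or more in at least 3 libraries. That left 16672 genes at stage 10.5 and 15594 at stage 12. All 15 libraries of a stage entered 1 fit with a mean per group, each comparison was a contrast of those means, tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p of 0.05 or less. Adjusted p-values in the text are limma's unless another tool is named. The comparisons were dorsal with ventral, left with right, dorsal with whole, ventral with whole, the mean of left and right (sagittal half-embryos) with whole, and that mean with the mean of dorsal and ventral, at each stage. The change of an effect between stages was tested in 1 fit of all 30 libraries over 14948 genes in both tables. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 8.29 to 12.6 between replicates at stage 10.5 and 6.82 to 11.9 at stage 12. The labels do not say that replicates come from separate clutches, so p-values measure the spread between these samples, which may be partly technical.

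Replicate numbers paired the samples. In each control's label the same-numbered half-embryos are named as the ones it serves, and deviations from group means correlated between same-numbered libraries at 0.414 or more (median 0.534) over 30 pairs at stage 10.5 and at 0.274 or more (median 0.411) over 30 pairs at stage 12, while other pairs lay at -0.157 or less and -0.0832 or less. All 15 libraries of each stage correlated best with their own number. The fit without a block had been chosen before the data were examined and was kept for the values in the text, and the fit with the number as a block is given beside a result where it moved a count by over 1.5 times or changed a call.

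Lists of genes were fixed from textbook knowledge before the data were examined, 17 in all: organizer, ventral BMP pathway, marginal zone mesoderm, endoderm, neural plate, epidermis, multiciliated cells, germ plasm, pluripotency, wound and immediate early, heat shock and chaperones, hypoxia and glycolysis, p53 and apoptosis, cell cycle, histones, ribosomal proteins and left-right asymmetry. Members were matched by the symbol in the gene ID without its homeolog suffix (.L or .S) or, for model IDs, by the deposited human symbol, and each copy was 1 member. Lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, in 198 tests, of which 108 passed and 19 passed with an estimated correlation. No scaling changed the sign of a called list's median. Human symbols come from the closest protein and can name a paralog, and reads shared between homeologs or near-identical models cannot be told apart in these tables, so values of a single copy are uncertain.

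Named genes followed a rule fixed before the data were examined: per comparison the 6 highest and 6 lowest fold changes among called genes with an average log2(RPKM + 1) of at least 1 and a gene symbol, homeologs sharing a place, and up to 4 members with the smallest p of each list discussed. A few genes chosen by this rule are not reported here. Genes named outside it are said to be chosen after their values were seen. The alternatives set at the same time were a pseudocount of 0.1, upper-quartile scaling, quantile normalization, no filter, the replicate block, only the groups compared in the fit, half-embryos averaged per number, and leaving out each library and each number. limma-voom on the recovered reads, with and without the block, reads thinned to 1 depth, list members matched by ID alone, list tests on averaged half-embryos and fits without libraries that stood apart were added after seeing the data. No scaling moved the median of all genes by more than 0.1 on the log2 scale. Simulations from these libraries (16672 and 15594 genes at stages 10.5 and 12) changed 50 genes each 1.5-, 2-, 4- and 8-fold. They were drawn from genes with a mean log2(RPKM + 1) of at least 1, so the shares do not cover lower genes. Of 2-fold genes the fit without a block recovered 74% and 50% for sagittal against whole at stages 10.5 and 12. For dorsal against ventral it recovered 52% and 42%. With the block these were 88%, 60%, 76% and 56%. False calls were 1, 0, 0 and 1 without the block and 7, 4, 8 and 7 with it, in that order. Tables and plots were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.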

Results

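Poly(A) RNA was sequenced from 30 libraries of Xenopus laevis, the African clawed frog, whose bisected embryo can restore a complete body pattern. The series concerns regeneration of twin embryos. At each of 2 stages, early gastrula (stage 10.5) and late gastrula (stage 12), 5 groups of 3 libraries were compared: undivided whole embryos, and left, right, dorsal and ventral half-embryos cut at stage 8, the blastula. Left and right half-embryos came from a cut along the midline, after which each can develop into a twin. Dorsal and ventral half-embryos came from a cut between the dorsal side, which holds the Spemann organizer, and the ventral side. The deposited RPKM tables listed 16673 genes at stage 10.5 and 15596 at stage 12. Whole-embryo libraries held 3532883 to 3739329 reads in listed genes at stage 10.5 and half-embryo libraries 3814623 to 5813109. At stage 12 the ranges were 2091772 to 2920488 and 2526910 to 5071874 reads, and whole embryos had the lowest mean depth of the 5 groups at both stages. Fold changes below are differences of mean log2(RPKM + 1) with their standard errors, which understate the change of genes at low RPKM, and RPKM values are means ± SD, all with n = 3 libraries per group. Beside counts of called list members, list alone gives the calls adjusted over that list alone, and block the calls with the replicate number as a block, where it moved a count by over 1.5 times or from 0.

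The comparison of dorsal with ventral half-embryos asked which genes differed between the sides of the embryo after their separation. At stage 10.5 organizer genes were far higher in dorsal half-embryos. Chordin, a secreted BMP antagonist, was listed at 133 ± 10.7 RPKM in dorsal and 0.380 ± 0.282 in ventral half-embryos for the CHRD model Xelaev18029538m, a log2 fold change of 6.62 ± 0.35 (limma adjusted p = 4.84e-07). The homeobox gene goosecoid (gsc.L) stood at 35.8 ± 10.1 and 0.396 ± 0.204 RPKM (4.70 ± 0.41, adjusted p = 7.89e-05). Sizzled (szl.L), a ventral secreted protein that feeds back on BMP signalling, went the other way, at 4.01 ± 3.79 RPKM in dorsal and 164 ± 67.4 in ventral half-embryos (-5.22 ± 0.51, adjusted p = 0.000147).

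Of 31 measured members of the organizer list at stage 10.5, 24 rose, 0 fell and 7 were not called (list alone 29 up and 1 down, block 25 up and 1 down) in dorsal over ventral half-embryos, among them the BMP ligand admp.S (4.56 ± 0.51), the secreted Wnt and multi-ligand inhibitors dkk1.S (4.35 ± 0.38) and cer1.L (4.28 ± 0.46), and hhex.S (3.48 ± 0.51). The camera adjusted p was 6.55e-102, and 0.000986 with an estimated correlation. The gene listed as crx.S, whose closest human protein in the deposited table is OTX2, rose by 3.51. In the ventral BMP list of 23, 0 rose, 13 fell and 10 were not called (list alone 0 up and 18 down) (camera adjusted p = 3.81e-48, and 0.000986 as the p with an estimated correlation), including the BMP targets msx1.S (-3.24 ± 0.31), bambi.L (-2.51 ± 0.30) and msx2.L (-2.48 ± 0.49). Of 21 neural plate genes, 8 rose, 0 fell and 13 were not called (list alone 15 up and 1 down), with irx1.L (2.25), ZIC2 (Xelaev18015642m) (1.77) and sox11.S (1.2) among them. Camera on this list gave adjusted p = 3.55e-32, and 0.00118 with an estimated correlation. Of 23 epidermal genes, 0 rose, 12 fell and 11 were not called (list alone 0 up and 17 down), including the keratin krt12.S (-2.89 ± 0.56) and the homeobox genes dlx3.S (-3.15 ± 0.43) and dlx5.S (-1.80), with the AP-2 model TFAP2A (Xelaev18031635m) at -1.48. The list's camera adjusted p was 1.65e-36, and 0.00135 with an estimated correlation.

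Mesodermal genes went both ways at stage 10.5. Of 31 marginal zone genes, 3 rose, 4 fell and 24 were not called (list alone 7 up and 11 down, block 5 up and 9 down): the myogenic gene myf5.L (2.92) was higher dorsally, and the Wnt ligand wnt8a.L (-1.11) and mespb.S (-1.28) were higher ventrally. Its camera adjusted p was 0.0301, and 0.551 with an estimated correlation. Among 26 endoderm genes, 1 rose, 2 fell and 23 were not called (list alone 4 up and 3 down, block 3 up and 3 down), with the model NODAL (Xelaev18018866m) (2.02) higher dorsally and the homeobox genes mixer.S (-1.02) and mix1.L (-1.32) lower (camera adjusted p = 0.164). Of 13 pluripotency genes, 2 rose, 0 fell and 11 were not called (list alone 6 up and 0 down), both being copies of foxd3, foxd3.S (2.99) and foxd3.L (2.85), which is also a neural crest gene. As a list they had camera adjusted p = 9.52e-13, and 0.00237 with an estimated correlation. The 44 wound and immediate early genes held 2 calls (block 1 up and 5 down), both lower dorsally, KLF2 (Xelaev18025218m) (-1.48) and KLF4 (Xelaev18023103m) (-1.68) (camera adjusted p = 0.422). The left-right list shared the same NODAL model as its only call among 10 members, and block 3 up and 1 down. By camera this list had adjusted p = 0.00248, and 0.291 with an estimated correlation. The multiciliated list had 5 members with 1 call, foxj1.L (1.6) (block 1 up and 1 down), and its camera adjusted p of 0.0479 became 0.258 as a p with an estimated correlation and 0.0664 with the replicate block. No member was called in the lists of germ plasm (camera adjusted p = 0.554), heat shock (0.554), hypoxia (0.14, block 2 up and 0 down), p53 (0.322), cell cycle (0.429), histone (0.0949) or ribosomal protein genes (0.323).

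In all, limma called 165 of 16672 genes between dorsal and ventral half-embryos at stage 10.5, 100 higher and 65 lower dorsally, of which 143 differed at least 2-fold. With the replicate number as a block it called 362 (189 and 173), and every one of the 165 was among them. A fit with only these 6 libraries called 102. The count was 96 without dorsal library 1, 84 without dorsal library 3 and 78 without ventral library 3.

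At stage 12 dorsal and ventral half-embryos again differed, with the epidermal and ciliated cell programs on the ventral side. Among genes with a symbol, the largest differences in dorsal half-embryos were in crx.L (6.16 ± 1.00, adjusted p = 0.00302), admp.L (6.04 ± 0.92), lrig3.L (4.53 ± 0.46), irx1.L (4.37 ± 0.54), dkk1.S (4.23 ± 0.58) and the neural homeobox gene nkx6-2.L (4.23 ± 0.60). On the ventral side szl.L reached 351 ± 79.1 RPKM against 6.73 ± 6.79 dorsally (-5.89 ± 0.92), followed among genes with a symbol by foxi1.S (-3.86 ± 0.62), a forkhead gene of ionocytes and early epidermis, the keratin gene krt.L (-3.74 ± 0.47), dlx3.S (-2.87 ± 0.45), foxf1.S (-2.75 ± 0.45), a gene of lateral plate mesoderm, and bambi.L (-2.69 ± 0.36). MCIDAS, the regulator that starts the multiciliated cell program, was listed at 0.224 ± 0.387 RPKM dorsally and 18.7 ± 8.03 ventrally for the model Xelaev18010956m (-3.98 ± 0.38, adjusted p = 0.00039).

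Of 34 organizer genes at stage 12, 29 rose, 0 fell and 5 were not called (list alone 31 up and 0 down), with CHRD models at 7.06 to 7.51. Camera gave the list adjusted p = 1.38e-54, and 0.00913 with an estimated correlation. In the ventral BMP list of 25, 0 rose, 15 fell and 10 were not called (list alone 0 up and 18 down), including msx1.L (-2.47) and GATA2 (Xelaev18023995m) (-2.15). With camera the list had adjusted p = 2.63e-23, and 0.00815 with an estimated correlation. Neural plate genes numbered 23, of which 15 rose, 0 fell and 8 were not called (list alone 20 up and 0 down), with zic1.S (3.98), irx2.L (3.96), irx2.S (3.49) and zic1.L (2.97) having the smallest p. For it camera gave adjusted p = 4.79e-35, and 0.0064 with an estimated correlation. Among 23 epidermal genes, 0 rose, 18 fell and 5 were not called (list alone 0 up and 21 down), including krt12.S at 98.0 ± 50.4 RPKM dorsally and 476 ± 57.3 ventrally (-2.38) and grhl3.1 (-2.21). This list had camera adjusted p = 1.37e-34, and 0.0064 with an estimated correlation. All 8 calls among 11 multiciliated genes were lower dorsally, MCIDAS (Xelaev18010956m) (-3.98), foxn4.S (-1.84), MCIDAS (Xelaev18008287m) (-3.23) and ccno.L (-2.42) having the smallest p, and 11 fell adjusted over the list alone. The whole list had camera adjusted p = 9.24e-21, and 0.0142 with an estimated correlation. Of 13 pluripotency genes, 6 rose, 0 fell and 7 were not called (list alone 8 up and 0 down), among them foxd3.L (2.99) and the neural genes sox2.1 (1.80) and SOX3 (Xelaev18042169m) (1.13). Camera on this list gave adjusted p = 3.44e-11, and 0.0064 with an estimated correlation.

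Marginal zone mesoderm genes at stage 12 again split between the sides: of 37, 9 rose, 7 fell and 21 were not called (list alone 14 up and 15 down, block 10 up and 11 down), with myod1.L (1.92), myf5.L (2.95) and eomes.S (2.32) higher dorsally and mespb.S (-1.71) lower (camera adjusted p = 0.74). Of 21 endoderm genes, 3 rose, 1 fell and 17 were not called (list alone 4 up and 3 down, block 4 up and 2 down), with nodal.L (3.38) and gata4.L (1.37) among those higher dorsally and mix1.L (-2.37) lower (camera adjusted p = 0.536). The glycolytic regulator pfkfb3 gave both calls of the 33 hypoxia genes, pfkfb3.L (1.61) and pfkfb3.S (1.37) (camera adjusted p = 0.2). Both calls of the 57 cell cycle genes were copies of the phosphatase gene cdc25b, cdc25b.S (1.66) and cdc25b.L (0.90). The list's camera adjusted p was 5.79e-05, and 0.0418 with an estimated correlation. In the germ plasm list rtn3.S (0.93) was the 1 call of 13, and block 2 up and 0 down. Its camera adjusted p was 0.00261, and 0.228 with an estimated correlation. In the histone list h1f0.L (1.03) was the 1 call of 93 (camera adjusted p = 0.994). Of 46 wound and immediate early genes, 2 rose, 3 fell and 41 were not called (list alone 3 up and 6 down, block 4 up and 6 down), with dusp1.S (1.39) and MYC (Xelaev18032361m) (-1.33) among them (camera adjusted p = 0.74). None of the 149 ribosomal protein genes was called, and their list was lower dorsally with a median of -0.08. As a list they had camera adjusted p = 0.00158, and 0.661 with an estimated correlation. Neither the heat shock (camera adjusted p = 0.187) nor the p53 list (0.2) held a call.

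Late dorsal and ventral half-embryos differed in 587 of 15594 genes by limma, 314 higher and 273 lower dorsally, 486 of them at least 2-fold. With the replicate number as a block the count was 898 (452 and 446). It was 305 without ventral library 1 and 342 without dorsal library 2.

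**Figure D1:**
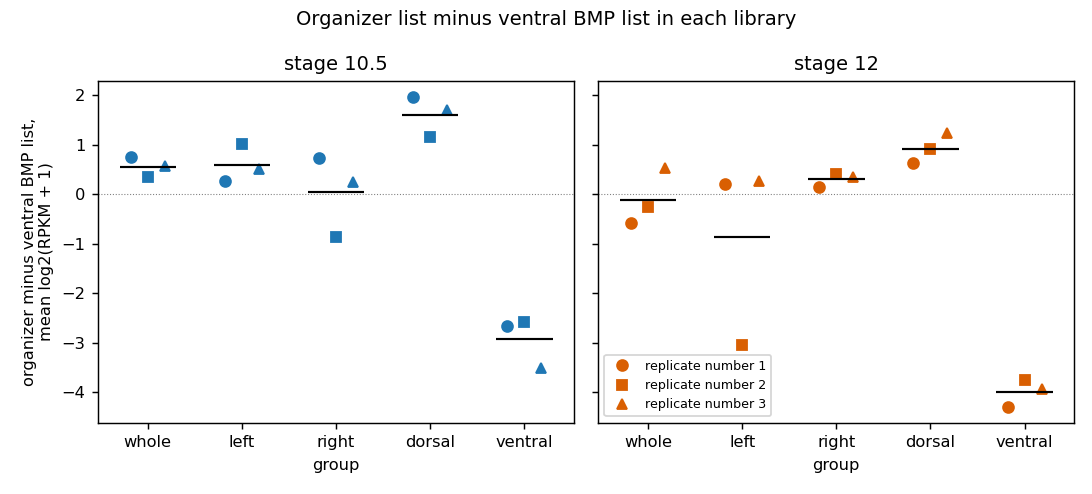
Each point is one library, placed by the mean log2(RPKM + 1) of the organizer list minus that of the ventral BMP list, with groups on the horizontal axis, 1 panel per stage, symbols for replicate numbers and black bars for group means. Dorsal half-embryos lay at 1.15 to 1.97 and ventral at -3.50 to -2.59 at stage 10.5, and at 0.62 to 1.22 and -4.30 to -3.75 at stage 12, where left library 2 stood at -3.05.

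Each dorsal and ventral half-embryo was next compared with the undivided embryo, its control in the labels. Dorsal half-embryos at stage 10.5 had less of the ventral and epidermal markers than whole embryos, as with szl.L (-2.87 ± 0.51), dlx3.S (-2.79 ± 0.43, 18.5 ± 4.40 RPKM in whole and 1.95 ± 1.35 in dorsal) and krt12.S (-2.52 ± 0.56), while no organizer gene was called (block 1 up and 1 down). Among genes with a symbol the strongest rises were in azin2.1 (2.19 ± 0.28), whose closest human protein in the deposited table is ornithine decarboxylase, the purine salvage enzyme gene pnp.L (2.03 ± 0.37), the tubulin gene tubb.L (1.91 ± 0.39), apoc1-like.L (1.91 ± 0.44), the myogenic gene myod1.L (1.62 ± 0.39) and dynll1.S (1.49 ± 0.26). Other falls were in the proton pump gene tcirg1.L (-2.24 ± 0.36), the oxygen-sensing prolyl hydroxylase gene egln3.L (-2.07 ± 0.49) and hs3st1.L (-1.88 ± 0.47). Of 23 epidermal genes, 0 rose, 5 fell and 18 were not called (list alone 0 up and 17 down, block 0 up and 18 down). By camera this list had adjusted p = 1.35e-08, and 0.326 with an estimated correlation. Of 23 ventral BMP genes, 0 rose, 5 fell and 18 were not called (list alone 1 up and 8 down, block 1 up and 10 down), including bambi.S (-1.44) and bambi.L (-1.33). Camera gave the list adjusted p = 0.00428, and 0.407 with an estimated correlation. The organizer, with 0 of 31 called, had camera adjusted p = 4.32e-05, the mesoderm list, with wnt11b.L (0.78) and myod1.L (1.62) called of 31 (block 12 up and 1 down), 5.22e-05, the neural plate list 0.0177 (block 1 up and 0 down), the histone list 1.6e-07 (3 up and 3 down, block 18 up and 6 down) and the wound list 0.00721 (3 up and 2 down, block 8 up and 3 down). Their adjusted p with an estimated correlation was 0.326 for histones and 0.407 for each of the other 4. Of 149 ribosomal protein genes 1 was called, rps16.L (0.60) (block 42 up and 0 down), and 142 had a positive value. With camera the list had adjusted p = 3.86e-14, and 0.407 with an estimated correlation. The pluripotency list passed with the replicate block alone (0 called, block 4 up and 0 down, camera adjusted p = 0.0743, 0.0414 with the block, and 0.407 with an estimated correlation). Of 57 cell cycle genes, 3 rose, 4 fell and 50 were not called (list alone 4 up and 9 down, block 16 up and 14 down), with CDC20 (Xelaev18025163m) (-0.74), mcm3.L (-1.01), WEE2 (Xelaev18002463m) (-0.91) and CCNB1 (Xelaev18008213m) (-1.12) having the smallest p (camera adjusted p = 0.299).

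Dorsal half-embryos differed from whole embryos in 705 genes by limma at stage 10.5, 169 higher and 536 lower, and in 4219 (1286 and 2933) with the replicate number as a block. Shares moved with scaling, to 253 higher and 384 lower after upper-quartile scaling and 225 and 296 after quantile normalization. A fit of these 6 libraries alone called 0 genes. Single libraries moved this count, which was 286 without whole-embryo library 1, 284 without dorsal library 1, 155 without dorsal library 2, 25 without whole-embryo library 3 and 17 without dorsal library 3.

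Ventral half-embryos at stage 10.5 had lower levels of organizer transcripts than whole embryos, with gsc.L at 0.396 ± 0.204 RPKM against 36.2 ± 11.9 (-4.69 ± 0.41), cer1.L (-4.49 ± 0.46), admp.S (-4.31 ± 0.51), dkk1.S (-3.69 ± 0.38), crx.S (-3.37 ± 0.26), hhex.S (-2.72 ± 0.51) and CHRD models at -5.96 to -5.79. Among genes with a symbol, the largest rises were in szl.L (30.5 ± 8.67 RPKM in whole and 164 ± 67.4 in ventral, 2.35 ± 0.51), evx1.L (2.34 ± 0.52), azin2.1 (2.28 ± 0.28), cdx2.L (2.16 ± 0.35), msx2.L (2.15 ± 0.49) and msx1.L (2.1 ± 0.30). Among 31 organizer genes, 0 rose, 22 fell and 9 were not called (list alone 0 up and 28 down). For it camera gave adjusted p = 1.33e-32, and 0.0464 with an estimated correlation. Among 23 ventral BMP genes, 8 rose, 0 fell and 15 were not called (list alone 17 up and 0 down, block 17 up and 0 down). This list had camera adjusted p = 1.15e-16, and 0.0464 with an estimated correlation. Of 31 mesoderm genes, 6 rose, 0 fell and 25 were not called (list alone 17 up and 4 down, block 17 up and 3 down), including cdx2.L (2.16), t.S (0.59), cdx4.L (1.69) and wnt8a.S (1.06) (camera adjusted p = 6.33e-09). Of 21 neural plate genes, 0 rose, 7 fell and 14 were not called (list alone 0 up and 13 down, block 0 up and 13 down), including irx1.L (-1.95), sox11.L (-1.08) and sox11.S (-1.16) (camera adjusted p = 1.52e-08). For both lists adjusted p = 0.096 with an estimated correlation. Both pluripotency calls among 13 members were falls, foxd3.L (-2.32) and foxd3.S (-2.40) (block 0 up and 5 down, camera adjusted p = 0.00252). The histone list had 1 call of 93, h1foo.L (-1.03) (block 10 up and 6 down, camera adjusted p = 5.25e-06). For these, adjusted p = 0.192 with an estimated correlation. Wound genes with a call were MYC (Xelaev18032361m) (2.2) and gadd45a.S (0.87) of 44, and block 8 up and 0 down. The whole list had camera adjusted p = 7.2e-05, and 0.307 with an estimated correlation. The epidermal (0.00132, block 4 up and 2 down) and ribosomal protein lists (2.41e-14, block 35 up and 0 down) passed camera with no member called without the block, and had adjusted p = 0.369 with an estimated correlation. Of 32 hypoxia genes, 0 rose, 3 fell and 29 were not called (list alone 0 up and 7 down, block 4 up and 8 down), namely pfkfb3.L (-1.12), pfkfb3.S (-0.95) and egln3.S (-1.24) (camera adjusted p = 0.249).

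In this comparison limma called 343 genes, 109 higher and 234 lower in ventral half-embryos, and 2895 (990 and 1905) with the replicate number as a block. Quantile normalization moved the split to 119 higher and 155 lower. A fit of the 6 libraries alone called 52. With 1 library left out the count was 98 without whole-embryo library 1, 115 without ventral library 2, 79 without whole-embryo library 3 and 47 without ventral library 3.

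At stage 12 dorsal half-embryos had more slc16a6-like.L, a transporter of the monocarboxylate family, than whole embryos (11.9 ± 1.35 against 0.384 ± 0.194 RPKM, 3.23 ± 0.33), and more arrdc3.L (2.22 ± 0.27), the cytoplasmic actin gene actg1.S (2.15 ± 0.26), pik3ip1.L (2.11 ± 0.35), rgs2.L (2.00 ± 0.28) and tspan1.L (1.92 ± 0.39). Epidermal transcripts were lower, as with foxi1.S (-3.07 ± 0.62), krt.L (-2.74 ± 0.47) and krt12.S (98.0 ± 50.4 against 340.0 ± 36.1 RPKM, -1.90 ± 0.30), and so were the enzyme genes cpox-like.L (-2.07 ± 0.42) and asl.L (-1.97 ± 0.37) and the prolyl hydroxylase gene egln2.L (-1.74 ± 0.25). Of 23 epidermal genes, 0 rose, 3 fell and 20 were not called (list alone 0 up and 13 down, block 0 up and 8 down). Camera on this list gave adjusted p = 1.19e-11, and 0.375 with an estimated correlation. The ventral BMP list held 1 call of 25, GATA2 (Xelaev18023995m) (-1.33), list alone 9 down and block 0 up and 8 down. The list's camera adjusted p was 0.000137, and 0.436 with an estimated correlation. Of 34 organizer genes 1 rose, frzb.S (0.86), and block 2 up and 0 down. Its camera adjusted p was 0.000171, and 0.652 with an estimated correlation. Among 57 cell cycle genes, 3 rose, 1 fell and 53 were not called (list alone 7 up and 1 down, block 6 up and 2 down), including mcm4.S (1.03) and mcm4.L (0.92). As a list they had camera adjusted p = 0.0145, and 0.436 with an estimated correlation. Of 33 hypoxia genes, 1 rose, 2 fell and 30 were not called (list alone 1 up and 6 down, block 1 up and 5 down), with egln3.L (-1.71) and egln3.S (-1.21) lower and vegfa.L (1.51) higher. By camera this list had adjusted p = 0.0438, adjusted p = 0.652 with an estimated correlation, and 0.103 with the block. The multiciliated (0.000276, block 0 up and 2 down), pluripotency (0.0074, block 1 up and 0 down), wound (0.00198, block 7 up and 0 down), histone (0.00773, block 1 up and 1 down) and ribosomal protein lists (0.00198, block 4 up and 0 down) passed camera with no member called without the block, at adjusted p = 0.414 to 0.67 with an estimated correlation.

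The count at stage 12 was 127 genes by limma, 59 higher and 68 lower in dorsal half-embryos, and 1041 (495 and 546) with the replicate number as a block. Splits were 102 and 72 after upper-quartile scaling, and 107 and 81 after quantile normalization. A fit of the 6 libraries alone called 24, limma-voom 61. The count was 35 without whole-embryo library 1, 24 without dorsal library 1, 256 without whole-embryo library 2, 29 without dorsal library 2, 19 without whole-embryo library 3 and 64 without dorsal library 3.

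Ventral half-embryos at stage 12 had lower neural and organizer transcripts than whole embryos, with CHRD models at -6.86 to -6.43 and, lowest among genes with a symbol, crx.L (-6.57 ± 1.00), admp.L (-5.36 ± 0.92), zic1.S (-4.36 ± 0.40), irx2.L (-4.11 ± 0.40), lrig3.L (-4.01 ± 0.46) and prdm14.S (-3.99 ± 0.62). Genes with a symbol that rose most were szl.L (3.62 ± 0.92), dlx2.S (3.11 ± 0.47), tbx2.S (2.86 ± 0.62), slc16a6-like.L (2.77 ± 0.33), the BMP target id2.S (2.46 ± 0.57) and rasl11b.S (2.31 ± 0.38). Of 34 organizer genes, 0 rose, 23 fell and 11 were not called (list alone 0 up and 30 down) (camera adjusted p = 9.81e-28). Of 23 neural plate genes, 0 rose, 16 fell and 7 were not called (list alone 0 up and 18 down) (camera adjusted p = 1.24e-24). With an estimated correlation these were adjusted p = 0.104 and 0.063. In the ventral BMP list of 25, 8 rose, 0 fell and 17 were not called (list alone 15 up and 0 down, block 14 up and 1 down), with evx1.L (2.15) and msx1.L (1.57) among them. Camera gave the list adjusted p = 5.87e-09, and 0.127 with an estimated correlation. Of 23 epidermal genes, 1 rose, 0 fell and 22 were not called (list alone 11 up and 0 down, block 3 up and 0 down), the call being GATA3 (Xelaev18017847m) (1.81). With camera the list had adjusted p = 2.35e-08, and 0.154 with an estimated correlation. Of 11 multiciliated genes, 3 rose, 0 fell and 8 were not called (list alone 11 up and 0 down), namely MCIDAS (Xelaev18010956m) (2.25), ccno.L (1.75) and foxn4.S (1.1). For it camera gave adjusted p = 6.72e-09, and 0.153 with an estimated correlation. Of 149 ribosomal protein genes 3 rose, rpl8.S (0.81), RPS3 (Xelaev18016414m) (0.56) and RPL11 (Xelaev18028961m) (1.12), and block 15 up and 0 down. This list had camera adjusted p = 2.35e-08, and 0.417 with an estimated correlation.

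Of 13 pluripotency genes, 0 rose, 4 fell and 9 were not called (list alone 0 up and 5 down), foxd3.L (-2.01), SOX3 (Xelaev18042169m) (-0.89) and sox2.1 (-1.57) among them. The whole list had camera adjusted p = 0.000134, and 0.104 with an estimated correlation. Hypoxia genes numbered 33, of which 0 rose, 5 fell and 28 were not called (list alone 1 up and 9 down, block 1 up and 8 down), with pfkfb3.L (-1.85), egln3.L (-1.71), pfkfb3.S (-1.14) and egln3.S (-1.22) having the smallest p. Camera on this list gave adjusted p = 0.00244, and 0.341 with an estimated correlation. Among 46 wound genes, 5 rose, 1 fell and 40 were not called (list alone 11 up and 2 down, block 11 up and 2 down), including MYC (Xelaev18032361m) (1.81) and gadd45a.S (0.94) higher and dusp1.L (-0.75) lower. The list's camera adjusted p was 0.00298, and 0.417 with an estimated correlation. Histone calls were h1f0.L (-1.27) and H3F3B (Xelaev18045270m) (-0.41) of 93, and block 6 up and 3 down. Its camera adjusted p was 0.013, and 0.59 with an estimated correlation. Of 37 mesoderm genes, 6 rose, 9 fell and 22 were not called (list alone 9 up and 13 down), with myod1.L (-1.91) and myf5.L (-3.04) lower and cdx2.L (1.58) higher (camera adjusted p = 0.595). Of 21 endoderm genes, 2 rose, 3 fell and 16 were not called (list alone 4 up and 8 down, block 4 up and 8 down) (camera adjusted p = 0.0583, 0.0268 with the block, and 0.499 with an estimated correlation).

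For ventral half-embryos at stage 12 limma called 616 genes, 225 higher and 391 lower than in whole embryos, and 1734 (751 and 983) with the replicate number as a block. A fit of the 6 libraries alone called 345. Single libraries moved this count, which was 303 without whole-embryo library 1, 213 without ventral library 1, 263 without whole-embryo library 3 and 277 without ventral library 3.

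Left and right half-embryos, the paired products of a midline cut, were compared to ask whether the twins differ. No gene was called between them: limma called 0 of 16672 genes at stage 10.5, where limma-voom called 0 and the replicate block 0. An unadjusted p under 0.05 was found for 107, where 834 would be expected with no difference. None of the 10 genes of the left-right asymmetry list was called. As a list they had camera adjusted p = 0.0208, and 0.41 with an estimated correlation. At stage 12 the counts were 0 of 15594 by limma, 0 by limma-voom and 0 with the block. An unadjusted p under 0.05 was found for 219, where 780 would be expected with no difference. Fewer than expected at both stages mean that the fit without a block was conservative here, so 0 calls do not show that the sides are alike. Only 4 left-right genes were measured at stage 12, too few for a list test. The organizer list was higher on the left at stage 10.5, with a median of 0.40 (camera adjusted p = 2.66e-15, and 0.305 with an estimated correlation). Right library 2 had an organizer minus ventral index of -0.86 where the other 5 left and right libraries had 0.24 to 1.02. Without that library the organizer list had camera adjusted p = 0.905, and the lists that passed were epidermis (median -0.21, camera adjusted p = 0.00165), germ plasm (-0.32, 7.39e-15), histone (0.18, 1.62e-06), mesoderm (-0.08, 0.0472) and ribosomal protein genes (-0.07, 0.000738). Leaving out the same library gave 3 called genes. Left library 2 at stage 12 had an index of -3.05, near the ventral half-embryos. With it the organizer list was lower on the left, at a median of -0.72 (camera adjusted p = 3.88e-16, and 0.131 with an estimated correlation), and without it camera gave adjusted p = 0.829. Passing without it were ribosomal protein genes (median 0.22, camera adjusted p = 3.92e-30), endoderm (-0.45, 4.77e-06), wound (-0.17, 0.00298), histone (0.16, 0.00532), epidermis (0.15, 0.0246) and germ plasm genes (-0.30, 0.0359), of which the ribosomal protein, epidermis and wound lists had the opposite sign at stage 10.5. Over all libraries 10 of 17 lists passed camera at stage 10.5 and 13 of 16 at stage 12, and none passed with an estimated correlation. The stage 12 histone list passed with the replicate block alone (camera adjusted p = 0.0689, 0.0179 with the block, and 0.701 with an estimated correlation).

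The comparison of left and right half-embryos together with whole embryos addressed what changes when a half-embryo regenerates as a twin. At stage 10.5 no member of the organizer (block 0 up and 2 down), ventral BMP (block 4 up and 0 down), neural plate (block 1 up and 1 down) or epidermis lists was called, and genes outside these lists differed. Among genes with a symbol, the largest rises were in azin2.1, at 111 ± 22.0 RPKM in whole, 501 ± 99.7 in left and 535 ± 167 in right half-embryos (2.19 ± 0.24, adjusted p = 0.00304), tubb.L (1.77 ± 0.34), the dynein light chain gene dynll1.S (1.24 ± 0.22), the zinc finger gene znf703.L (1.24 ± 0.19), the posterior homeobox gene cdx2.L (1.23 ± 0.30) and the centriole gene poc1a.L (1.21 ± 0.20). The largest falls among them were in egln3.L, at 26.0 ± 15.2 RPKM in whole, 5.33 ± 2.36 in left and 5.34 ± 2.11 in right (-2.02 ± 0.43, adjusted p = 0.0309), tcirg1.L (-1.91 ± 0.31), hes3-like.S (-1.73 ± 0.30), tmem169-like.L (-1.46 ± 0.19), slc25a44.S (-1.40 ± 0.27) and snx17.L (-1.30 ± 0.25).

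Of 32 hypoxia and glycolysis genes at stage 10.5, 0 rose, 4 fell and 28 were not called (list alone 0 up and 5 down, block 5 up and 7 down), namely both copies of the mitophagy gene bnip3, bnip3.L (-0.92) and bnip3.S (-0.90), and of egln3, egln3.L (-2.02) and egln3.S (-1.12) (camera adjusted p = 0.633). Among 57 cell cycle genes, 2 rose, 4 fell and 51 were not called (list alone 8 up and 5 down, block 16 up and 12 down), with CDC20 (Xelaev18025163m) (-0.68), mcm3.L (-0.76) and WEE2 (Xelaev18002463m) (-0.69) lower and the replication clamp PCNA (Xelaev18018556m) (0.86) higher (camera adjusted p = 0.132). In the heat shock list of 18, 2 rose, 1 fell and 15 were not called (list alone 3 up and 1 down, block 4 up and 2 down), with hspa8.L (0.72) and hspa8.S (0.52) higher and HSP90B1 (Xelaev18021302m) (-0.43) lower (camera adjusted p = 0.24). Mesoderm genes had positive values in 29 of 31 members and a median of 0.37: 1 rose, 0 fell and 30 were not called (list alone 6 up and 0 down, block 14 up and 0 down), the call being cdx2.L (1.23). By camera this list had adjusted p = 7.5e-08, and 0.481 with an estimated correlation. Ribosomal protein genes were positive in 139 of 149 at a median of 0.26, with rps16.L (0.56) the 1 call, and block 49 up and 0 down. Camera gave the list adjusted p = 3.88e-14, and 0.569 with an estimated correlation. Wound genes gave 1 call of 44, gadd45a.S (0.73), and block 10 up and 1 down. With camera the list had adjusted p = 0.000321, and 0.569 with an estimated correlation. The oocyte linker histone gene h1foo.L (-0.88) fell and HIST2H2AB (Xetrov90022557m.L) (0.61) rose among 93 histone genes, and block 10 up and 6 down. For it camera gave adjusted p = 3.68e-05, and 0.569 with an estimated correlation. Camera passed none of the remaining lists, with or without the block: organizer (adjusted p = 0.566), ventral BMP (0.24), neural plate (0.304), epidermis (0.815), endoderm (0.991), multiciliated (0.141), germ plasm (0.835), pluripotency (0.304), p53 (0.781) and left-right (0.835).

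Sagittal half-embryos differed from whole embryos in 452 genes by limma at stage 10.5, 146 higher and 306 lower, with 125 at least 2-fold apart, and in 3666 (1236 and 2430) with the replicate number as a block. The split was 239 and 220 after quantile normalization and 94 and 447 by limma-voom on recovered reads. A fit of the 9 libraries alone called 16, left and right averaged per number 8. With 1 library left out the count was 103 without whole-embryo library 1, 284 without left library 2, 263 without right library 2, 19 without whole-embryo library 3, 145 without left library 3 and 153 without right library 3. If the labels hold, bisection and medium changed together in every comparison with whole embryos.

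At stage 12 the largest rise of a gene with a symbol in left and right half-embryos was in slc16a6-like.L, at 0.384 ± 0.194 RPKM in whole, 8.15 ± 3.34 in left and 13.1 ± 4.57 in right (2.98 ± 0.29, adjusted p = 0.00126). It was followed by actg1.S (1.96 ± 0.23, 82.7 ± 8.14 RPKM in whole embryos), azin2.1 (1.88 ± 0.20), arrdc3.L (1.67 ± 0.24), rgs2.L (1.6 ± 0.24) and the immune checkpoint ligand gene cd274.L (1.41 ± 0.29). Lowest among genes with a symbol were ankrd37.L, a known hypoxia target, at 13.6 ± 14.4 RPKM in whole, 0.287 ± 0.290 in left and 1.51 ± 1.92 in right (-2.71 ± 0.54, adjusted p = 0.0358), the prolyl hydroxylase genes egln2.L (-1.80 ± 0.22) and egln3.L (-1.66 ± 0.24), slc25a34.L (-1.74 ± 0.38), the sterol synthesis gene cyp51a1.L (-1.64 ± 0.37) and fam46c.L (-1.61 ± 0.29). Of 33 hypoxia genes, 0 rose, 4 fell and 29 were not called (list alone 1 up and 9 down, block 2 up and 7 down), the same bnip3 and egln3 copies as at stage 10.5, egln3.S (-1.14), bnip3.S (-1.21) and bnip3.L (-1.35) beside egln3.L. This list had camera adjusted p = 0.0201, adjusted p = 0.791 with an estimated correlation, and 0.0662 with the block. Among 57 cell cycle genes, 6 rose, 1 fell and 50 were not called (list alone 11 up and 2 down, block 11 up and 4 down), including the replication genes mcm4.S (1.02), mcm4.L (0.92) and PCNA (Xelaev18018556m) (0.68) against CDC20 (Xelaev18025163m) (-0.65). The whole list had camera adjusted p = 0.0201, adjusted p = 0.791 with an estimated correlation, and 0.061 with the block.

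In the endoderm list at stage 12, GATA5 (Xelaev18043514m) (-1.36) was the 1 call of 21 (block 0 up and 5 down, camera adjusted p = 0.0139). Wound genes had 1 call of 46, gadd45a.S (0.76) (block 7 up and 0 down, camera adjusted p = 0.0201). Ribosomal protein genes had 2 calls of 149, rpl8.S (0.57) and RPS21 (Xelaev18043517m) (0.86) (block 9 up and 1 down, camera adjusted p = 0.00328). None of 93 histone genes was called (block 6 up and 2 down, camera adjusted p = 0.00328). The pluripotency list had no call and a camera adjusted p of 0.0375, or 0.061 with the block. For all of these lists adjusted p = 0.791 with an estimated correlation. Of 13 germ plasm genes 1 fell, rtn3.S (-0.88) (block 0 up and 2 down, camera adjusted p = 0.641). No member was called among the organizer (median -0.29, camera adjusted p = 0.208, block 1 up and 0 down), ventral BMP (median -0.17, 0.0827, block 0 up and 1 down), neural plate (median -0.13, 0.641) and epidermis lists (median -0.24, 0.0653, block 0 up and 1 down), and left library 2, at an organizer minus ventral index of -3.05 against 0.15 to 0.41 in the other 5 left and right libraries, entered these values.

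Over 15594 genes limma called 215 at stage 12, 114 higher and 101 lower in sagittal half-embryos, 114 at least 2-fold apart, and 1323 (640 and 683) with the replicate number as a block. With libraries thinned to 1 depth it called 111 (65 and 46). The split was 142 and 82 after upper-quartile scaling, and 49 and 83 by limma-voom. A fit of the 9 libraries alone called 22, left and right averaged per number 19. The count was 11 without whole-embryo library 1, 105 without left library 1, 400 without whole-embryo library 2, 91 without left library 2, 65 without right library 2, 21 without whole-embryo library 3, 65 without left library 3 and 52 without right library 3.

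**Figure D2:**
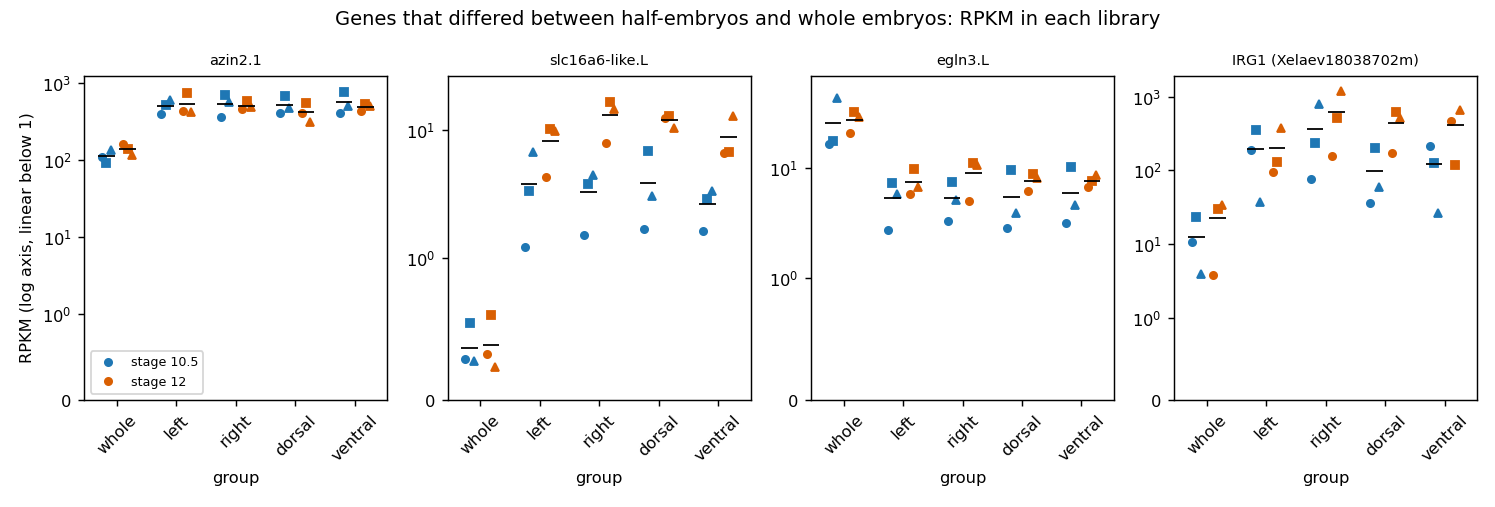
RPKM of 4 genes in each library on a log axis that is linear below 1, with groups on the horizontal axis, colours for stages and black bars for group means. The azin2.1 values were 91.2 to 135 in whole embryos and 358 to 767 in half-embryos at stage 10.5. At stage 12 slc16a6-like.L was at 0.230 to 0.602 in whole embryos and 4.30 to 16.6 in half-embryos. IRG1 was chosen after its values were seen.

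The mean of left and right half-embryos was also set against the mean of dorsal and ventral half-embryos, which asks whether the plane of the cut matters among embryos that were all bisected. At stage 10.5 the 4 called genes were 3 chordin models, higher in sagittal half-embryos, and Xelaev18000342m, a model with no symbol. CHRD (Xelaev18029538m) stood at 86.4 ± 33.7 RPKM in left, 61.6 ± 29.1 in right, 133 ± 10.7 in dorsal and 0.380 ± 0.282 in ventral half-embryos, against 83.7 ± 7.68 in whole embryos (2.35 ± 0.25, adjusted p = 0.00344), with CHRD (Xelaev18027421m) at 2.28 ± 0.25 and CHRD (Xelaev18027420m) at 2.38 ± 0.29. Means of logs lower the mean of dorsal and ventral half-embryos for any gene that differs between these sides, so values in this comparison do not by themselves show an effect of the plane. With the half-embryos of each number averaged as RPKM before the log the CHRD models stood at 0.07 to 0.20 and Xelaev18000342m at -2.87, and 0 genes were called in this fit, which leaves 3 against 3. Xelaev18000342m was at 4.03 ± 3.1 RPKM in left, 5.59 ± 4.62 in right, 18.6 ± 2.49 in dorsal and 50.5 ± 3.29 in ventral half-embryos (-2.71 ± 0.40, adjusted p = 0.0466), and was chosen after its values were seen.

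Of 31 organizer genes at stage 10.5, 3 rose, 0 fell and 28 were not called (list alone 11 up and 0 down) (camera adjusted p = 2.05e-34, and 0.037 with an estimated correlation), all 3 being the chordin models. No member was called in the neural plate list of 21 (median 0.27, camera adjusted p = 1.68e-14, and 0.037 with an estimated correlation) or the pluripotency list of 13 (median 0.23, camera adjusted p = 2.1e-06, and 0.0412 with an estimated correlation). With the half-embryos averaged as RPKM the medians of these 3 lists were 0.16, 0.20 and 0.15, and the adjusted p with an estimated correlation 0.0518, 0.0518 and 0.139. The ventral BMP (camera adjusted p = 0.000795), epidermis (0.000531), cell cycle (0.0106), histone (0.00458), ribosomal protein (0.0269), p53 (0.0364) and left-right lists (0.0217) passed camera with no call, and had adjusted p of 0.419 or more with an estimated correlation. With that averaging the epidermis (median -0.03, camera adjusted p = 0.813), left-right (0.0977) and ribosomal protein lists (0.0532) did not pass, and the endoderm (median -0.13, 0.000234), germ plasm (0.14, 0.00404) and mesoderm lists (-0.14, 0.00126) did, at 0.28 or more with an estimated correlation. With the replicate block the left-right list was at 0.0732 and the mesoderm list passed (camera adjusted p = 0.198, 0.0253 with the block, and 0.703 with an estimated correlation). The calls numbered 4 by limma, 3 higher and 1 lower, 13 (6 and 7) with the replicate block, and 0 by limma-voom. An unadjusted p under 0.05 was found for 447 genes, where 834 would be expected with no difference. The split was 3 and 2 after upper-quartile scaling and 3 and 0 after quantile normalization. A fit of the 12 half-embryo libraries alone called 2. Single libraries moved this count, which was 9 without right library 2.

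At stage 12 the 2 called genes were the homeobox model GBX2 (Xelaev18047278m), chosen after its values were seen, and recql.L, a DNA helicase gene, both higher in sagittal half-embryos. GBX2 (Xelaev18047278m) stood at 4.33 ± 0.747 RPKM in left, 4.90 ± 0.776 in right, 1.35 ± 0.335 in dorsal and 0.915 ± 0.437 in ventral half-embryos (1.41 ± 0.15, adjusted p = 0.00515), and recql.L at 6.38 ± 0.627, 7.83 ± 2.47, 2.27 ± 0.567 and 2.17 ± 0.386 RPKM in the same order, against 2.65 ± 0.804 in whole embryos (1.32 ± 0.17, adjusted p = 0.0167). Of 23 neural plate genes none was called and 19 rose adjusted over the list alone (median 0.77, camera adjusted p = 3.13e-40, and 0.00784 with an estimated correlation). Of 13 pluripotency genes none was called and 4 rose adjusted over the list alone. Camera on this list gave adjusted p = 3.48e-09, and 0.00784 with an estimated correlation. Medians were 0.72 for the organizer (camera adjusted p = 1.1e-18, and 0.143 with an estimated correlation), -0.37 for the ventral BMP (6.62e-11, and 0.105 with an estimated correlation) and -0.46 for the multiciliated list (1.6e-08, and 0.143 with an estimated correlation). With the block the endoderm list passed (camera adjusted p = 0.133, and 0.0487 with the block) and the epidermis list did not (0.0414, and 0.0628 with the block), both at 0.62 with an estimated correlation. With the half-embryos of each number averaged as RPKM, medians were 0.51 (neural plate), 0.21 (pluripotency), 0.16 (organizer), -0.50 (ventral BMP), -0.84 (multiciliated), -0.38 (epidermis) and -0.11 (endoderm, camera adjusted p = 0.0196), with an adjusted p of 0.102 or more at an estimated correlation. Other tools called 1 (limma-voom) and 2 genes (the replicate block), 7 were called at a pseudocount of 0.1 and 0 with the half-embryos averaged per number, where GBX2 (Xelaev18047278m) stood at 1.39 and recql.L at 1.33. The count was 72 without left library 2, which stood at an organizer minus ventral index of -3.05, 6 without ventral library 2, and 1 without any one of left libraries 1 and 3, right library 1, dorsal libraries 1 and 3, and ventral libraries 1 and 3.

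The heading of the authors' deposited table describes a selection of genes over 2-fold higher in both sagittal half-embryos than in whole embryos and also higher there than in the other half-embryos, with a further 2-fold criterion on dorsal or ventral half-embryos whose direction its wording leaves open. By that heading in the authors' deposited table, 9 of 16672 genes at stage 10.5 and 25 of 15595 at stage 12 remained. From group means alone, 236 genes at stage 10.5 and 292 at stage 12 were at least 2-fold over whole embryos in both left and right half-embryos. Of these, 20 and 16 were also above both dorsal and ventral half-embryos and 2-fold over at least one of them. limma called 6 of the 20 and 1 of the 16 against whole embryos (12 and 2 with the block), and 0 and 1 against dorsal and ventral half-embryos. The mirror selection, dorsal and ventral half-embryos over whole embryos and over left and right ones, gave 10 and 19 genes.

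The tables of both stages hold different libraries, and 14947 genes were tested in both. Between dorsal and ventral half-embryos, 91 genes were higher and 46 lower at both stages, where independent lists would share 1.82 and 0.981 (151 and 121 with the block, against 4.72 and 4.27). Between sagittal half-embryos and whole embryos, 43 genes were higher and 30 lower at both stages, where independent lists would share 1.09 and 1.69 (315 and 359 with the block, against 51.2 and 91.2). Opposite directions at the stages were called for 0 genes in both comparisons, and with the block for 1 (dorsal against ventral) and 6 (sagittal against whole). The change of each effect from stage 10.5 to stage 12 was tested itself over 14948 genes. For sagittal half-embryos against whole embryos limma called 0 genes, and 792 had an unadjusted p under 0.05. With the replicate block 10 were called, all with a more positive value at stage 12. Among them were the origin recognition gene orc1.L (0.87 ± 0.16, adjusted p = 0.115, and 0.00603 with the block) and the histone methyltransferase model SUV39H1 (Xelaev18038114m) (0.98 ± 0.41, adjusted p = 0.937, and 0.00255 with the block). Values and standard errors of these changes are from the fit without the block. For dorsal against ventral half-embryos limma called 0, with 382 at an unadjusted p under 0.05, below a share of 0.05 of genes, and 4 with the block. Those 4, named after their values were seen like the genes before them, had adjusted p of 0.0523 to 0.0666 without the block. They were models PRDM1 (Xelaev18029311m) (1.71 ± 0.30, block adjusted p = 0.0357) and PRDM1 (Xelaev18027228m) (1.84 ± 0.35, block adjusted p = 0.0183), pdxdc1.L (-1.57 ± 0.27, block adjusted p = 0.0357) and foxj1.L (-3.36 ± 0.62, block adjusted p = 0.0366). The last, a regulator of motile cilia, had dorsal over ventral values of 1.6 at stage 10.5 and -1.77 at stage 12.

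**Figure D3:**
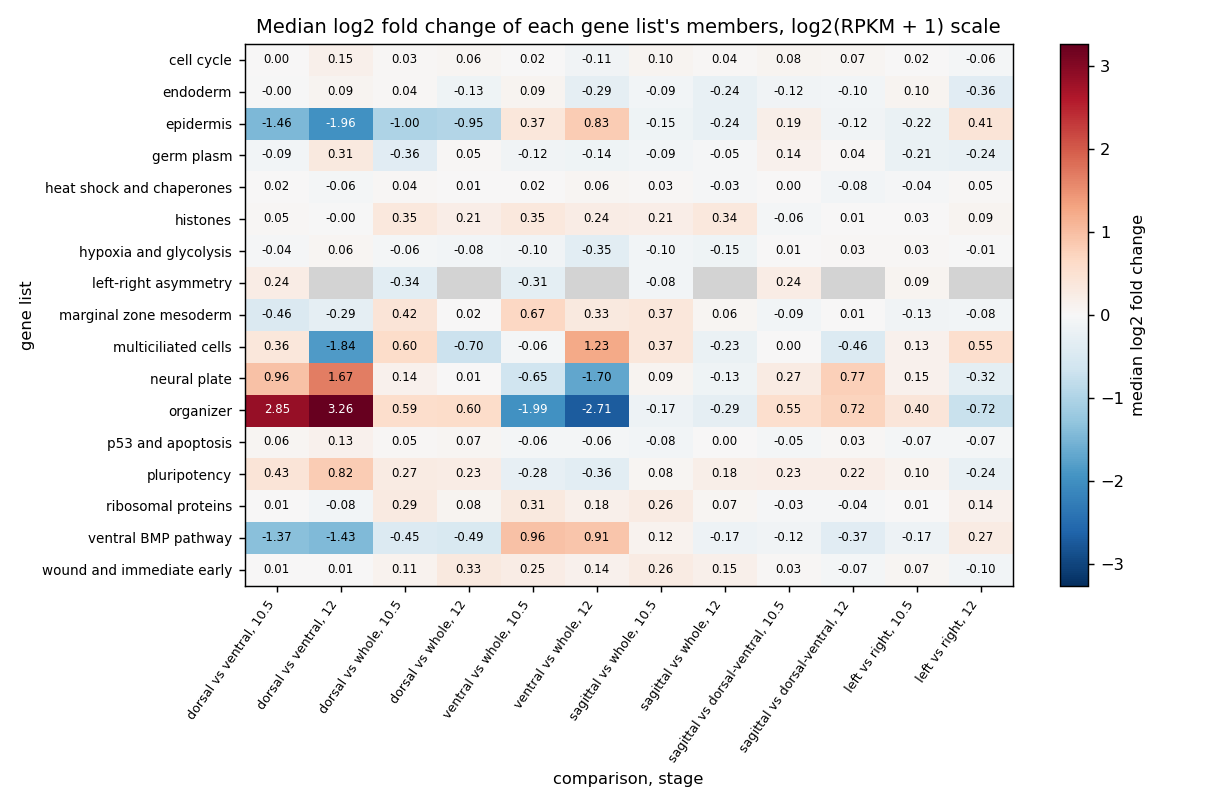
Colour gives the median log2 fold change over the members of each gene list (vertical axis) in each comparison and stage (horizontal axis), on the log2(RPKM + 1) scale, with blue below 0, red above and grey for a list with too few members. The organizer list stood at 2.85 and 3.26 in dorsal over ventral half-embryos and at -0.17 and -0.29 in sagittal half-embryos over whole embryos.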

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

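The limma-voom fits, the fits at 1 depth, the list tests with the block, with IDs alone or with half-embryos averaged, and the fits without right library 2 (stage 10.5) or left library 2 (stage 12) where these lay outside a comparison were chosen after the results were seen, and all others were planned. With the replicate block, which pairs libraries of the same number, limma called 3666 (sagittal against whole), 13 (sagittal against dorsal and ventral), 362 (dorsal against ventral), 4219 (dorsal against whole) and 2895 (ventral against whole) at stage 10.5, and 1323, 2, 898, 1041 and 1734 at stage 12, and 0 between left and right at both stages. Series of 5 counts below keep that order. Every gene called without the block was called with it, and beyond the values given beside the results it changed the call of no other list test and of no gene printed as not called. Why the block called more genes in comparisons with whole embryos was not tested beyond the correlations between same-numbered libraries. limma-voom on recovered reads called 541, 0, 159, 741 and 297 at stage 10.5, and 132, 1, 583, 61 and 482 at stage 12, and with the replicate block 3904, 27, 460, 4556 and 3106 at stage 10.5, and 1187, 14, 980, 951 and 1512 at stage 12. With only the groups compared in the fit, which leaves fewer libraries to estimate the spread, the counts were 16, 2, 102, 0 and 52 at stage 10.5, and 22, 2, 451, 24 and 345 at stage 12. With half-embryos averaged per number, which leaves 3 against 3, they were 8 and 19 for sagittal against whole and 0 and 0 for sagittal against dorsal and ventral half-embryos at stages 10.5 and 12.

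A pseudocount of 0.1 gave 386, 6, 162, 620 and 286 at stage 10.5, and 169, 7, 574, 122 and 581 at stage 12. Upper-quartile scaling gave 461, 5, 165, 637 and 343 at stage 10.5, and 224, 2, 587, 174 and 614 at stage 12, and no filter 453, 4, 165, 705 and 343 at stage 10.5, and 223, 2, 587, 131 and 618 at stage 12. Quantile normalization gave 459, 3, 159, 521 and 274 at stage 10.5, and 273, 2, 574, 188 and 620 at stage 12. For the change of an effect between stages, where limma called 0, upper-quartile scaling called 2 and the replicate block 10 for sagittal against whole, and upper-quartile scaling 4, a pseudocount of 0.1 9 and the replicate block 4 for dorsal against ventral. The cause of these differences was not tested. Of 198 list tests 108 passed, 19 with an estimated correlation, 29 by fry, which does not compare a list with other genes, 106 with the block in camera and 90 with members matched by ID alone. For sagittal against dorsal and ventral 20 list tests passed, and 21 with half-embryos averaged per number, of which 17 passed in both.

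Leaving out a library or a replicate number in turn gave 0 to 487 (sagittal against whole), 0 to 9 (sagittal against dorsal and ventral), 3 to 162 (dorsal against ventral), 0 to 3 (left against right), 0 to 553 (dorsal against whole) and 5 to 286 (ventral against whole) called genes at stage 10.5, and 1 to 400 (sagittal against whole), 0 to 72 (sagittal against dorsal and ventral), 0 to 637 (dorsal against ventral), 0 to 0 (left against right), 0 to 256 (dorsal against whole) and 0 to 722 (ventral against whole) at stage 12. Except for left against right, the lowest counts came from leaving out a number, which leaves 2 libraries per group. Without right library 2, which was outside these comparisons, the counts at stage 10.5 were 155 (dorsal against ventral), 553 (dorsal against whole) and 286 (ventral against whole), and without left library 2 at stage 12 they were 637, 131 and 652. Of the genes chosen by the naming rule, 31 of 44 for dorsal against ventral at stage 10.5 and 52 of 63 at stage 12 stayed called with each single library left out, against 4 of 27 and 5 of 26 for sagittal against whole, and with the block all of these stayed called. None of these genes changed direction under any alternative run.

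Depth also set counts. All libraries of a stage were thinned to the reads of the shallowest one. The 5 counts were then 360, 5, 154, 615 and 275 at stage 10.5, and 111, 3, 514, 92 and 461 at stage 12. For sagittal against whole 337 and 103 were also called at full depth.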

Other observations

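Tests and genes in this part were chosen after the results were seen, apart from the hypoxia list test and from bnip3, egln3, mcm3.L and h1foo.L, which the rule for named genes gave. Gene models whose human match is IRG1, the enzyme that makes itaconate in activated macrophages, were among the genes with the highest fold changes between bisected and whole embryos. Model IRG1 (Xelaev18038702m) stood at 12.6 ± 9.73 RPKM in whole, 193 ± 158 in left and 369 ± 379 in right half-embryos at stage 10.5 (4.03 ± 0.91, limma adjusted p = 0.0378), and at 22.6 ± 16.4, 201 ± 157 and 623 ± 527 at stage 12 (4.01 ± 0.79, adjusted p = 0.0358). The models IRG1 (Xelaev18038693m) and IRG1 (Xelaev18038707m) were higher as well, by 4.14 ± 0.90 and 4.41 ± 0.88 at stage 10.5 and 4.33 ± 0.74 and 4.13 ± 0.70 at stage 12. Dorsal and ventral half-embryos differed from whole embryos in 3 of 3 IRG1 models at stage 12 and in 0 of 3 at stage 10.5, where 3 of 3 were called with the replicate block, and in sagittal against dorsal and ventral half-embryos 0 of 3 were called at either stage. Models with neighbouring IDs that match YRDC, which acts in tRNA modification, were called in 3 of 3 at stage 10.5 and 0 of 3 at stage 12 (2 of 3 with the block) in sagittal half-embryos over whole embryos, and those that match PHYHD1 in 1 of 3 and 2 of 3 (3 of 3 with the block at both), with PHYHD1 (Xelaev18038704m) at 3.67 ± 0.68 (adjusted p = 0.0187) and 3.14 ± 0.46 (adjusted p = 0.00938). Near-identical models can share reads, so these are not independent genes.

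Among genes lower in sagittal half-embryos than in whole embryos at both stages were both copies of the collagen lysyl hydroxylase model PLOD1, at -1.98 ± 0.28 for PLOD1 (Xetrov90018273m.L) and -1.27 ± 0.26 for PLOD1 (Xetrov90018273m.S) at stage 10.5 and -2.41 ± 0.36 and -2.11 ± 0.35 at stage 12. The zygotic replication gene zmcm3.L rose by 1.00 ± 0.13 at stage 10.5 (adjusted p = 0.00451, 30.7 ± 7.24 RPKM in whole, 61.2 ± 1.05 in left and 61.6 ± 6.21 in right), while its maternal counterpart mcm3.L was at -0.76 ± 0.12 (adjusted p = 0.0134) and the oocyte histone gene h1foo.L at -0.88 ± 0.15 (adjusted p = 0.0142). Its more abundant copy h1foo.S, at -0.51 ± 0.33 (adjusted p = 0.415), was called with the block alone (adjusted p = 0.00364), and the maternal gene btg4 was not called, at -0.14 ± 0.29 for btg4.L and 0.29 ± 0.29 for btg4.S. At stage 12 zmcm3.L was at 0.74 ± 0.15 (adjusted p = 0.0358), mcm3.L at -0.22 ± 0.26 (adjusted p = 0.737) and h1foo.L at -0.37 ± 0.43 (adjusted p = 0.739). All 4 mitochondrial models had positive values, of which 0 were called at stage 10.5 and 2 at stage 12, and 4 with the block at each stage, among them ND5 (Xelaev18003734m) at 1.02 ± 0.29 (adjusted p = 0.0703, and 2.23e-05 with the block) and 1.56 ± 0.35 (adjusted p = 0.0460).

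Left library 2 at stage 12 stood at an organizer minus ventral index of -3.05, against 0.145 to 0.414 in the other 5 left and right libraries. A swap with the ventral half-embryo of the same number was argued against, since that library lay at -3.75, among the ventral ones. Another ventral half-embryo under this label was argued against less firmly, since the library lay 0.70 above the highest of the 3 ventral libraries, whose SD of 0.283 rests on 3 values. A cut beside the midline may also give such a library, and its partner right library lay 0.0784 above the higher of the other right libraries, within the SD of 0.107 among the other 5 libraries, so the test does not decide. No biological explanation was tested, and the library was kept in the values of the text.

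Both copies of bnip3 and of egln3, which are induced under hypoxia, were lower in sagittal half-embryos than in whole embryos at both stages, 8 calls with a median of -1.18. They are 4 of 32 or 33 hypoxia genes that went both ways, with 15 positive and 17 negative at stage 10.5 (camera adjusted p = 0.633) and 13 and 20 at stage 12 (0.0201, 0.0662 with the block, and 0.791 with an estimated correlation). With all libraries thinned to 1 depth the median of the 8 calls was -1.23. Thinning keeps the expected RPKM, so this argues only against unequal sampling noise, not other effects of depth. Under the scaling that moved it most toward 0 the median was -1.14. No scaling moved the median of all genes by more than 0.1, too little to account for -1.18, which argues against a common scale factor. Half-embryos being ahead in development was argued against, since these genes changed by a median of 0.13 (SD 0.284) from stage 10.5 to 12 in dorsal and ventral half-embryos. Left open is that oxygen or medium differed between whole embryos and half-embryos, confounded with bisection by design.

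Across 14948 genes, which are not independent replicates, sagittal half-embryos minus whole embryos at stage 10.5 correlated with the change from stage 10.5 to 12 in dorsal and ventral half-embryos (Pearson r = 0.385, Spearman rho = 0.393). After thinning to 1 depth r was 0.383, which again argues only against unequal sampling noise. Half-embryos being ahead in development may account for it. The 9 libraries have 27 splits with 1 library per number as the smaller group. Of these 2, the real one included, gave as large an r. The other (0.393) kept 2 whole-embryo libraries there, overlapping the real split, so the splits do not decide. Medium was confounded here too.

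Other splits of the libraries were counted for each comparison. For sagittal half-embryos against whole embryos, with left and right as 1 group, 1 of 84 splits, the real one, gave as many called genes at each stage. It gave 787 genes against at most 22 at stage 10.5 and 287 against at most 7 at stage 12. At both stages the highest other split parted the 3 libraries of a replicate number from the rest. The 84 splits ignore the pairing by number. Among the 27 that take 1 library of each number as the smaller group, the real one alone gave as many, 1 of 27 at each stage. That makes a chance split unlikely without excluding it. For sagittal against dorsal and ventral half-embryos the real split gave 0 genes at stage 10.5, with the highest other at 905, a count that tests nothing as any split gives as many, and at stage 12 4 of 100 splits drawn from 462 gave as many (2 against up to 170), a share under 0.05 that rests on 2 genes. Splits with many more calls may follow the difference of dorsal and ventral half-embryos, and the split with most calls at stage 12 put 3 of the 4 libraries of a replicate number in 1 group. Among splits that take as many libraries of each number as the real one, the highest others were 1 and 1 for sagittal against whole and 3 and 1 for sagittal against dorsal and ventral half-embryos at stages 10.5 and 12. The 3 against 3 comparisons have 10 splits, too few for a share under 0.05. Real counts and the highest others were 165 and 0 (dorsal against ventral), 705 and 0 (dorsal against whole) and 343 and 1 (ventral against whole) at stage 10.5, with 1 of 10 splits as large in each, and 587 and 0, 127 and 0 and 616 and 0 at stage 12, again 1 of 10. Left against right gave 0 and 0 at both stages, which tests nothing either. For the change between stages, fitted on differences within numbers, the values were 0 and 0 for sagittal against whole, and 1 and 0 for dorsal against ventral, 1 of 10 splits.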
